A study of Gallus gallus with 16 samples.

How the data were processed

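RNA was measured in cells sorted from the vagal region of chicken embryos that had been electroporated with enhancer reporter constructs. As background, NC2 is an enhancer of FOXD3 and E2 an enhancer of SOX10, both transcription factor genes of the neural crest, the migratory cell population that leaves the dorsal neural tube. Per the labels, E2 cells carried the E2 reporter signal and not the NC2 signal, DP cells carried both, and negative cells carried neither. Stages are Hamburger-Hamilton (HH) stages of chick development. The earliest stage is HH10 in the sample records, whereas the series text and the column names of the count table give HH12; it is called HH10 here, and the table's HH12 columns were read as that stage because the other 2 stages match. Embryos were electroporated at HH4 for the earliest stage and at HH8 or HH9 for the later 2 stages, so that stage and electroporation time changed together. Sorted cells were lysed, total RNA was extracted, cDNA was made and amplified with a full-length low-input kit, and Nextera XT libraries were sequenced as short read pairs, per the labels' protocols.

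The deposited table holds raw read counts per gene for 16 libraries, 2 for each of 8 groups, with no normalization by the authors; the values are whole numbers and each library sums to a different total. Per the submitters' processing notes, the tools included STAR 2.4.2a, Subread 1.4.5 with featureCounts, and DESeq2, on the galGal5 genome build; the settings for strand and for reads with several matches are not given in the sources used here. Reads of overlapping or antisense genes and of near-identical gene copies may therefore be shared between genes. Genes carry Ensembl identifiers with exon coordinates, which are used here as the table gives them, on galGal5. The files do not pair the identifiers with gene names: the reference table of 25635 chicken genes matched 0 of them. For that reason SOX10, FOXD3 and the 25 gene lists written before the data were examined (neural crest, neuronal, glial, blood, muscle and other sets) could not be looked up, and none of their tests was run.

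Of the 24881 genes in the table, 7511 had no count in any library. These included all 5766 genes on 3635 of the 3670 sequences in the table, namely 3634 scaffolds and the mitochondrial genome with its 37 genes. No value from those sequences is read as absent expression. The shares of mitochondrial reads could not be computed for the same reason.

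Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, TMM normalization, filterByExpr at its defaults, which kept 14676 genes). All 16 libraries entered 1 fit with 8 group means and 8 residual degrees of freedom, since a pair of libraries per group gives too few alone. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. There were 13 comparisons, of which 10 set 2 groups against each other and 3 tested the difference between 2 such contrasts. This design and the rule for named genes were fixed before the data were examined, as were the alternatives other than those given as later choices. The labels do not say that the libraries of a group came from separate embryos or pools, so p-values measure the spread between these libraries, which may be technical. Counts per 1e6 counts (CPM) of single genes and of runs of genes were scaled by TMM, and those of chromosome W were not. Errors are SD over n = 2 libraries. A fold against a group with 0 counts is a lower bound computed against a floor of 3 counts over the group, the smaller of that from pooled counts and that from the mean of the libraries, and a fold against a group with few counts comes from pooled counts with its 95% counting interval. PCR duplicates were not removed by unique identifiers, so intervals and floors cover counting error only.

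The rule for named genes asked for gene symbols. It was applied without that condition and shortened to the 2 called genes with the highest and the 2 with the lowest log2 fold change in each comparison, among those with a mean of at least 5 CPM in the higher group and no overlap between the libraries of the groups compared; no overlap condition was used for tests of a difference between contrasts. Of 2 against 2 libraries, chance gives 1 of the 6 possible orders with every library of a given group above the other group.

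In place of the lists, gene groups were formed after the data were examined, from calls in libraries other than those of the comparison they were tested in: genes called at HH10 or HH18, and genes called between HH10 and HH25 negative cells. Chromosomes W and Z, genes with a genomic span of at least 73.3 kb and genes with a single exon interval were added. The 71 tests of these groups used camera in limma 3.58.1 with a preset correlation of 0.01 on log2 CPM (prior count of 2), adjusted together, with an estimated correlation and fry as alternatives. Overlaps of calls between stages used Fisher's exact test, only between comparisons without a library in common. This test counts genes as independent, so that its p-values overstate the evidence where genes vary together. Runs of 3 or more neighbouring tested genes called in the same direction were counted against 1000 shuffles of the calls over genes. The position of a library along the change in negative cells is the mean log2 CPM of the genes higher at HH25 than HH10 minus that of the genes lower, scaled to 0 at the mean of HH10 negative cells and 1 at that of HH25 negative cells.

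Total counts ranged from 4032540 to 45313160 per library. The tests were tried on simulated counts with each gene's mean over all libraries, its fitted dispersion and the real totals. All groups were equal except for 200 genes changed in the first-named group. The counts were drawn from the kind of model that the test fits, and no gene was set to 0 in a group or a library. The shares of false calls therefore do not carry over to the real data. In the simulation of HH18 DP minus E2 over 14247 genes, 64% of genes changed 16-fold, 48% of those changed 8-fold, 18% of those changed 4-fold and 0% of those changed 2-fold were called, and 3 of 68 calls were false. In that of HH25 DP minus E2 over 14285 genes the shares were 66%, 38%, 22% and 2%. The most false calls, 6 of 68, were made in the simulation of E2 HH25 minus HH18.

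Alternatives were DESeq2 size factors in edgeR, the DESeq2 1.42.0 Wald test, no filter, a stricter filter of 5 CPM in 2 libraries, fits on only the groups compared, replicate numbers as a block, each library left out in turn, and an adjusted p below 0.01 for overlaps. Libraries are named by the numbers in the table's column names, which for 3 groups (HH10 E2, HH10 negative and HH25 DP) are not those of the sample titles; these columns were tied to their group only. No pair of libraries matched within sampling noise, with a chi-square per degree of freedom between 25.4 and 200 for the 8 pairs.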

Results

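Gene expression was measured by RNA-seq in 16 libraries of cells sorted from the chick vagal region at HH10, HH18 and HH25. The vagal neural crest, which lies at the level of the hindbrain, is known to supply the enteric nervous system and parts of the outflow tract of the heart. Cells with E2 reporter signal alone (E2), cells with both reporter signals (DP) and cells with neither (negative) were collected, with 2 libraries per group and no DP group at HH10. Total counts per library were 22574825 and 39385794 for HH10 negative, 12416163 and 45313160 for HH10 E2, 7692817 and 4032540 for HH18 negative, 22141610 and 19310536 for HH18 E2, and 10838093 and 19164931 for HH18 DP cells. At HH25 they were 20261455 and 9153539 for negative, 10163592 and 10635494 for E2, and 12634040 and 37459288 for DP cells. Between 11693 and 15661 genes had counts in a library. The comparisons ask how labelled crest cells differ from their unlabelled neighbours, how DP differs from E2 cells, and how each population changes with stage.

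Except for HH25 DP cells, the populations followed stage along the first principal component of log2 CPM, which held 27.0% of the variance. It ran from the HH10 libraries, at -156 to -94.5, over the HH18 libraries, at -20.5 to 36.8, to the HH25 E2 libraries, at 59.2 and 103, and the HH25 negative libraries, at 142 and 186. The HH25 DP libraries lay at -14.2 and -36.7, within the range of the HH18 libraries or below it. Across genes, which are not independent replicates, the correlation of log2 CPM between the libraries of a group was lowest in HH25 negative cells (0.841), followed by HH10 E2 (0.870) and HH18 DP cells (0.881), and was highest in HH10 negative cells (0.960). A total of 4014 genes differed between HH25 and HH10 negative cells (1802 higher and 2212 lower at HH25). Along this change HH18 cells of each population lay between the ends, with positions of 0.379 ± 0.016 (SD, n = 2) for negative, 0.385 ± 0.12 for E2 and 0.439 ± 0.073 for DP cells. At HH25 the E2 cells had reached 0.639 ± 0.095, while the DP cells were at 0.255 ± 0.055. Without HH25 negative library 2 the HH18 DP, HH25 E2 and HH25 DP cells were at 0.350, 0.535 and 0.194, in the same order.

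**Figure D1:**
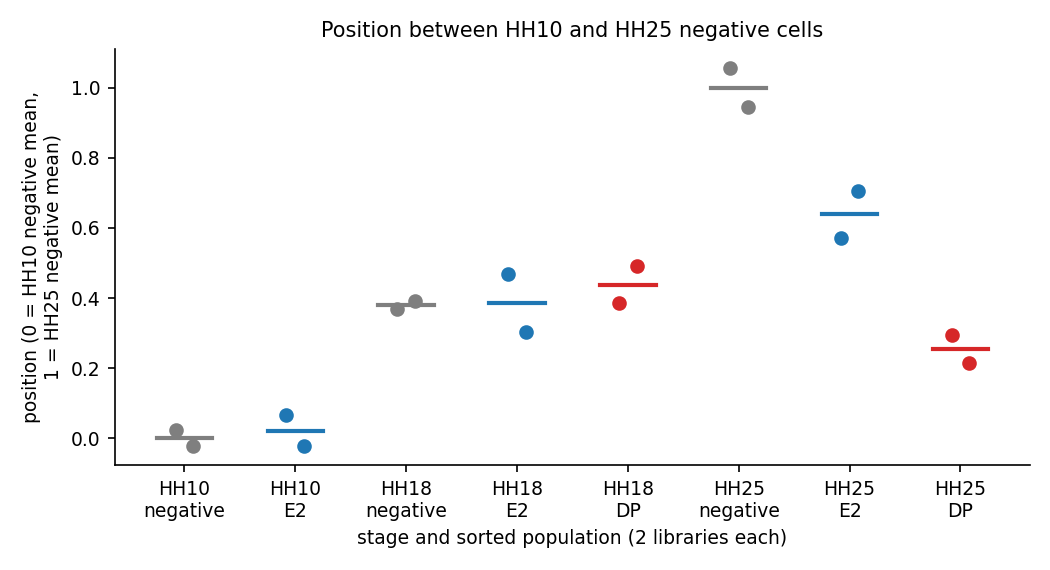
Position of each of the 16 libraries (points) and each group mean (bars) on a linear axis from the mean of HH10 negative cells (0) to that of HH25 negative cells (1), by stage and sorted population. The HH25 DP libraries, at 0.294 and 0.216, lie below each HH18 library (0.303 to 0.490).

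At HH10, most genes called between E2 and negative cells were lower in E2 cells. Of 243 genes called, 208 were lower and 35 higher in E2 cells (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted). The 208 lower genes included 104 with no count in either E2 library. Among them, ENSGALG00000006190 on chromosome 4 (4248504 to 4258576, plus strand, 6 exon intervals) had 55.0 ± 2.1 CPM in negative cells and 0 counts in E2 cells, at least 1116-fold lower (adjusted p = 0.012). ENSGALG00000003965 on chromosome 5 (2002977 to 2006676, minus strand, 4 exon intervals) was higher in E2 cells, at 15.6 ± 6.4 CPM against 0.260 ± 0.37 CPM, a ratio of 53.6 (35.2 to 85.9) in pooled counts (adjusted p = 0.018). ENSGALG00000003895 on chromosome 17 (6421491 to 6427617) was also higher, at 12.2 ± 4.1 against 0.189 ± 0.27 CPM. The HH10 E2 libraries held the fewest genes at equal depth: thinned to 4032540 counts they kept 11299 and 12179 genes, against 12187 to 14097 in the other 14 libraries. With only the 4 HH10 libraries in the fit 0 genes were called, with 1528 at an unadjusted p under 0.05, and DESeq2 on all libraries called 875. Without negative library 1 or 3 the count fell to 127 or 131, and the calls of ENSGALG00000006190 (without E2 library 3), ENSGALG00000003965 (without negative library 1) and ENSGALG00000003895 (without negative library 1 or E2 library 1) each ended.

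At HH18, E2 cells again differed from negative cells mainly by lower genes, with 108 lower and 8 higher among 116 called. A group of 3 neighbouring genes on one strand of chromosome 21 (6083120 to 6090874) had a summed level of 439 ± 46 CPM in negative and 21.5 ± 9.1 CPM in E2 cells, and no run of 3 genes was called without negative library 2, E2 library 1 or E2 library 2. ENSGALG00000003323 on chromosome 11 (2658956 to 2694119, minus strand, 9 exon intervals) was at 290 ± 196 CPM in negative cells, with 151 and 428 CPM in the libraries, and had no count in E2 cells, at least 3386-fold lower (adjusted p = 0.0069). The highest fold among higher genes was that of ENSGALG00000035557 on chromosome 12 (6139852 to 6142332), at 67.4 ± 40 CPM in E2 and 4.17 ± 2.0 CPM in negative cells, a ratio of 18.8 (13.7 to 26.3) in pooled counts (adjusted p = 0.023). Of the 108 lower genes, 12 were also among the 208 lower genes of HH10, where 1.53 would be shared by independent lists of these sizes (Fisher's exact test, adjusted p = 1.01e-07). At an adjusted p below 0.01 the lists shared 3 genes, where 0.310 would be shared (adjusted p = 0.012). As a set the 208 genes were lower in HH18 E2 cells (camera, adjusted p = 5.44e-06, 0.067 with an estimated correlation, and 0.0026 with fry). The count was 677 with only the HH18 E2 and negative libraries in the fit, 486 with DESeq2 and 193 without a filter. It was 36 and 42 without E2 library 1 or 2 and 52 without negative library 2, the call of ENSGALG00000003323 ended without either E2 library, and that of ENSGALG00000035557 without either negative library or E2 library 1.

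DP cells at HH18 differed from negative cells in 68 genes, 54 lower and 14 higher. ENSGALG00000003323 had no count in DP cells either, at least 2363-fold lower than in negative cells (adjusted p = 0.014). ENSGALG00000008896 on chromosome 7 (14159350 to 14200241, minus strand, 5 exon intervals) reached 325 ± 63 CPM in DP and 7.53 ± 1.9 CPM in negative cells, a ratio of 42.0 (34.0 to 52.5) in pooled counts (adjusted p = 0.014). ENSGALG00000008615 on chromosome 5 (24709933 to 24791051, minus strand, 29 exon intervals) reached 80.9 ± 15 against 1.99 ± 2.0 CPM. The count was 430 with DESeq2, 116 without a filter, 25 without negative library 2 and 22 without DP library 1. The call of ENSGALG00000003323 ended without negative library 2 or either DP library, and those of the other 2 genes ended without any 1 of the 4 libraries.

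DP and E2 cells at HH18 differed in 54 genes, of which 40 were higher and 14 lower in DP cells. The 40 higher genes had a median level of 115 and 126 CPM in the DP libraries and 5.96 and 3.31 CPM in the E2 libraries. Their median was 111 and 92.1 CPM in the HH18 negative libraries, close to the level in DP cells. In HH25 DP cells it was 6.96 and 5.33 CPM. The gene with the highest fold, ENSGALG00000011668 on chromosome 4 (51270481 to 51273558, plus strand, 4 exon intervals), had 109 ± 65 CPM in DP cells and no count in E2 cells, at least 1372-fold higher (adjusted p = 0.0055). The run of 3 genes on chromosome 21 that was lower in E2 than in negative cells stood at 773 ± 8.4 CPM in DP cells, and no run of 3 genes was called without any 1 of the 4 libraries. Among the 14 lower genes, ENSGALG00000005689 on chromosome 6 (17099350 to 17178107, minus strand, 11 exon intervals) had 13.1 ± 3.2 CPM in E2 and 0.127 ± 0.053 CPM in DP cells, a ratio of 94.7 (36.8 to 349) in pooled counts (adjusted p = 0.044). The count was 476 with DESeq2 (251 higher and 225 lower), 94 without a filter (67 and 27) and 39 with only these 4 libraries (38 and 1). It fell to 7 (7 and 0), 6 (5 and 1) and 27 (24 and 3) without E2 library 1, E2 library 2 and DP library 1, and the split was 24 and 20 without DP library 2. Leaving out either E2 library ended the call of ENSGALG00000011668, and leaving out any 1 of the 4 libraries ended that of ENSGALG00000005689.

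**Figure D2:**
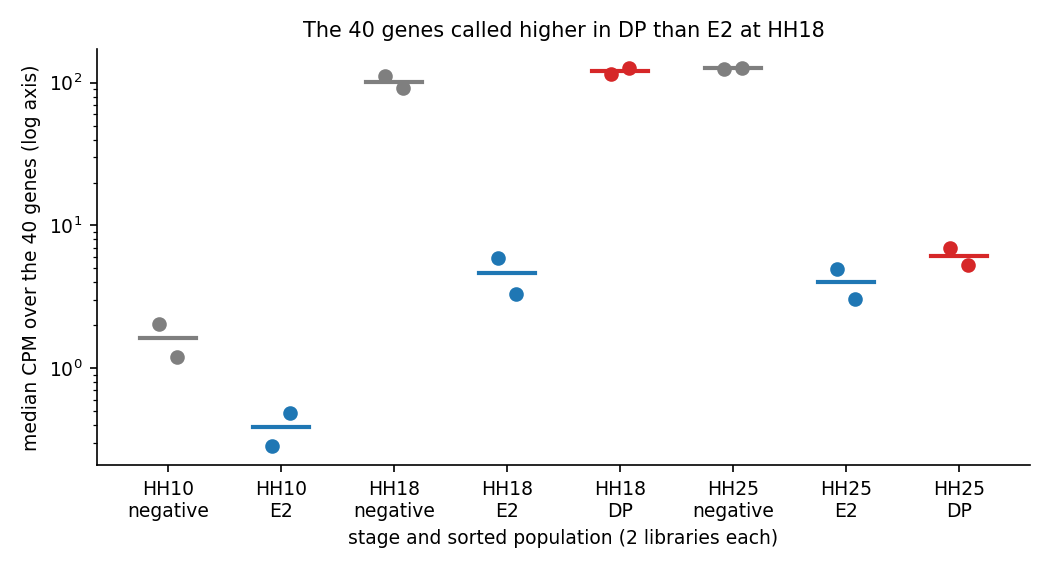
Median TMM-scaled CPM, on a log axis, of the 40 genes called higher in DP than E2 cells at HH18, in each library (points) with the mean of each group (bars). The genes were chosen on the HH18 DP and E2 libraries; the HH18 negative libraries, at 111 and 92.1 CPM, lie near the HH18 DP libraries, and the HH25 DP libraries, at 6.96 and 5.33 CPM, lie near the E2 libraries.

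At HH25 the E2 and negative cells differed in 422 genes, and most of these were higher in E2 cells (270 higher and 152 lower). The lower genes included transcripts that were abundant in negative cells. A group of 3 neighbouring genes on chromosome 3 (107900662 to 107917298) summed to 3389 ± 114 CPM in negative cells and to 0 in E2 cells. ENSGALG00000016668, the first of them (107900662 to 107906657, plus strand, 8 exon intervals), had 1678 ± 179 CPM in negative cells and was at least 11704-fold lower in E2 cells (adjusted p = 0.0013). A run of 3 genes on chromosome 2 (4018778 to 4026402) stood at 1538 ± 140 CPM in negative and 2.09 ± 1.6 CPM in E2 cells, and the run on chromosome 21 at 646 ± 28 and 5.33 ± 4.7 CPM. Genes this close together can be copies that share reads, so that the level of each is less certain than the sum. In the other direction, ENSGALG00000004936 on chromosome 4 (2023971 to 2030901, plus strand, 9 exon intervals) had 20.1 ± 11 CPM in E2 cells and no count in negative cells, at least 186-fold higher (adjusted p = 0.0048). The genes lower in E2 cells at HH18 were largely lower again: 71 of the 108 were called at HH25, where independent lists would share 1.12 (Fisher's exact test, adjusted p = 3.67e-120), and 36 were shared at an adjusted p below 0.01 (0.261 by independent lists). Of the 8 genes higher in E2 cells at HH18, 1 was higher again, where independent lists would share 0.147 (Fisher's exact test, adjusted p = 0.15). As a set the 108 genes were lower (camera, adjusted p = 8.73e-62, 0.0020 with an estimated correlation, and 6.96e-07 with fry). The count was 1492 with DESeq2 (901 higher and 591 lower) and 64 with only the HH25 E2 and negative libraries (3 and 61). It was 142 without E2 library 1 (71 and 71), 278 without E2 library 2 (219 and 59) and 703 without negative library 2 (549 and 154), so that higher genes were not the majority in 2 of these fits, while the calls of ENSGALG00000016668 and ENSGALG00000004936 passed with each of the 4 libraries left out and that of ENSGALG00000004936 ended with only these 4 libraries (adjusted p = 0.081).

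DP and negative cells at HH25 had the most calls of the 10 comparisons between 2 groups. Of 14676 genes, 3465 were called, 2003 higher and 1462 lower in DP cells. ENSGALG00000007466 on chromosome 4 (11210631 to 11219813, plus strand, 9 exon intervals) had 108 ± 11 CPM in DP cells and no count in negative cells, at least 1007-fold higher (adjusted p = 0.0013). ENSGALG00000004936, which was higher in E2 cells, had 60.4 ± 1.8 CPM in DP cells (adjusted p = 7.58e-04). ENSGALG00000019696 on chromosome 2 (4020689 to 4022467, minus strand, 4 exon intervals) fell from 705 ± 95 CPM in negative cells to no count in DP cells, at least 12861-fold lower (adjusted p = 2.36e-04). Of the 54 genes lower in DP than negative cells at HH18, 34 were lower again, where independent lists would share 5.38 (Fisher's exact test, adjusted p = 1.36e-20), and 20 were shared at an adjusted p below 0.01 (1.10 by independent lists). Called genes lay next to each other more often than in shuffles of the calls over genes. There were 77 runs of 3 or more neighbours called in 1 direction. The mean in 1000 shuffles was 44.8 (permutation test, p = 0.001, the smallest possible, adjusted p = 0.0026). The shuffles did not allow for traits that neighbours may share, such as span. Of the 1468 tested genes with a span of at least 73.3 kb, 216 were higher and 40 lower in DP cells. The camera adjusted p of this set was 0.043 (0.68 with an estimated correlation, and 0.071 with fry). Runs were fewer without negative library 1, DP library 2 or DP library 3, in fits that also called fewer genes. No shuffles were made for these fits, so that they do not show whether the excess of runs remains. The median log2 fold change over all genes was 0.19 with TMM and 0.03 with DESeq2 size factors, so that the split between higher and lower genes depends on the scaling; with the latter it was 1744 higher and 1649 lower. The count was 1760 without negative library 1, 2217 without DP library 2 and 1470 without DP library 3, and the calls of the 3 genes named here passed in each case.

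DP and E2 cells at HH25 differed in 953 genes, 570 higher and 383 lower in DP cells (473 higher and 444 lower with DESeq2 size factors). The majority of higher genes was absent with the stricter filter (648 and 654) and with DESeq2 (1452 and 1453). Of the 40 genes higher in DP than E2 cells at HH18, 3 were higher again, where independent lists would share 1.55 (Fisher's exact test, adjusted p = 0.20). Of the 14 lower genes, 3 were lower again, where independent lists would share 0.365 (adjusted p = 0.0074). Genes that were higher in HH25 than HH10 negative cells were mostly on the lower side. Of these 1802 genes, 311 were lower and 9 higher in DP cells. Their camera adjusted p was 1.20e-34 (0.096 with an estimated correlation, and 0.0043 with fry). Of the 2212 genes that were lower in HH25 than HH10 negative cells, 412 were higher and 8 lower in DP cells. For these the camera adjusted p was 1.24e-27 (0.10 with an estimated correlation, and 0.0036 with fry). The 23 tested genes of chromosome W, which in birds only females carry, were lower as a set in DP cells, with 1 gene called alone. This set had a camera adjusted p of 1.51e-05 (0.038 with an estimated correlation, and 0.0026 with fry). Counts on chromosome W amounted to 37.3 and 75.2 CPM in the DP libraries and to 309 and 261 CPM in the E2 libraries. ENSGALG00000013862 on chromosome 3 (54871262 to 54872083, plus strand, 2 exon intervals) had 13.5 ± 2.7 CPM in E2 cells and no count in DP cells, at least 247-fold lower (adjusted p = 0.0053). ENSGALG00000028230 on chromosome 1 (50843549 to 50848761, plus strand, 17 exon intervals) had 12.8 and 29.2 CPM in the DP libraries and no count in E2 cells, at least 146-fold higher (adjusted p = 0.024). A group of 3 neighbouring genes on chromosome 26 (1889290 to 2012259) summed to 490 ± 35 CPM in DP and 94.1 ± 22 CPM in E2 cells. This count rested on single libraries: edgeR called 0 genes without DP library 2 or DP library 3 (3267 and 2066 at an unadjusted p under 0.05), 8 without E2 library 2 (0 higher and 8 lower) and 624 without E2 library 1, whereas DESeq2 on all libraries called 2905 and the fit on these 4 libraries alone 1559. Without either DP library the calls of both named genes ended, and that of ENSGALG00000028230 ended without either E2 library too.

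**Figure D3:**
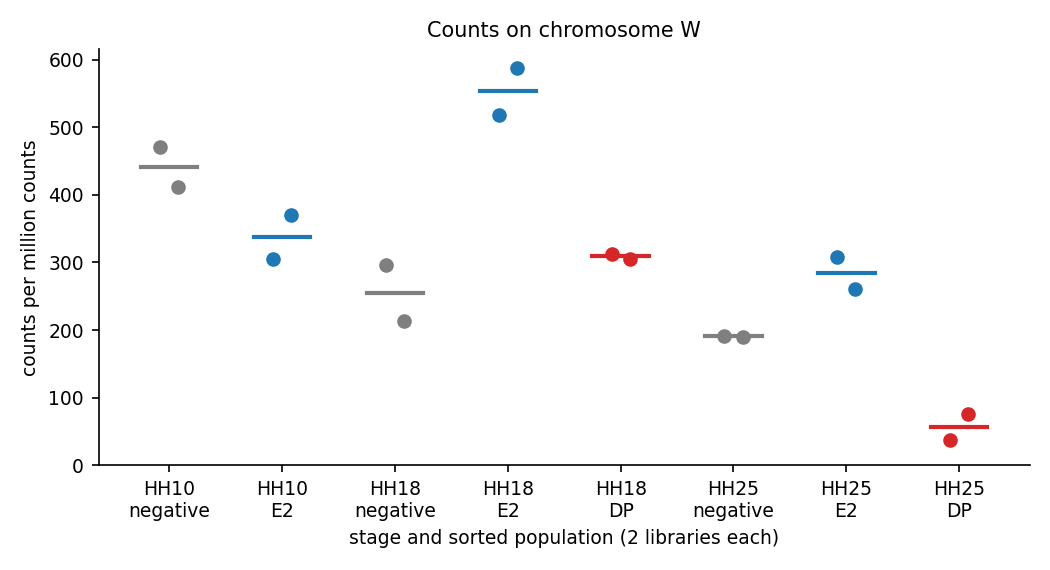
Counts on chromosome W in each library, in CPM, (points) and the mean of each group (bars), on a linear axis from 0. The HH25 DP libraries, at 37.3 and 75.2, lie below the other 14 libraries (190 to 588).

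Between HH10 and HH18, E2 cells gained more genes than they lost, with 558 higher and 153 lower at HH18 among 711 called. ENSGALG00000043480 on chromosome 4 (44451151 to 44550000, minus strand, 7 exon intervals) had 387 ± 33 CPM at HH18 and 1 count in the HH10 libraries, a ratio of 23864 (4282 to 942620) in pooled counts (adjusted p = 1.03e-06). ENSGALG00000005504 on chromosome 19 (8668217 to 8683224, minus strand, 8 exon intervals) went from 162 ± 26 CPM to no count, at least 2115-fold lower (adjusted p = 0.0056). Of the 558 higher genes, 237 had no count in either HH10 E2 library, the libraries with the fewest genes at equal depth. The count was 28 with only the HH10 and HH18 E2 libraries in the fit (16 higher and 12 lower) and 2181 with DESeq2 (1368 and 813). It was lower with any 1 of the 4 libraries left out. Electroporation was at HH4 for HH10 and at HH8 or HH9 for HH18, so that stage and electroporation time changed together. The calls of both named genes passed with each of the 4 libraries left out.

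Between HH18 and HH25, 63 genes were called in E2 cells, 40 higher and 23 lower at HH25. This was fewer than the 711 of the earlier interval, whereas fits on only the 4 libraries of each comparison called 89 in the later and 28 in the earlier interval. ENSGALG00000028908 on chromosome 2 (32684361 to 32690449, minus strand, 3 exon intervals) rose from no count to 14.5 ± 0.80 CPM, at least 203-fold higher (adjusted p = 0.0068). ENSGALG00000029669 on chromosome 21 (6086545 to 6088226), within the run of 3 genes described above, fell from 12.2 ± 4.4 to 0.241 ± 0.34 CPM, a ratio of 51.8 (22.1 to 160) in pooled counts (adjusted p = 0.019). In DP cells 139 genes were called, 56 higher and 83 lower at HH25. ENSGALG00000026790 on chromosome Z (26043375 to 26046985, plus strand, 4 exon intervals) rose from no count to 33.6 ± 2.9 CPM, at least 318-fold higher (adjusted p = 0.0027). The whole run on chromosome 21 fell in DP cells from 773 ± 8.4 to 3.17 ± 1.2 CPM. DESeq2 called 540 genes in E2 and 1233 in DP cells, and the fit without a filter 112 and 251. In E2 cells more genes were lower than higher without HH25 E2 library 1 (23 higher and 50 lower) and HH18 E2 library 1 (1 and 3). The E2 count was 4, 0 and 7 without HH18 E2 library 1, HH18 E2 library 2 (762 at an unadjusted p under 0.05) and HH25 E2 library 2, the first 2 of which ended both E2 calls named here and the last that of ENSGALG00000029669; the DP count was 67, 33 and 28 without HH18 DP library 1, HH25 DP library 2 and HH25 DP library 3, with ENSGALG00000026790 called in each case, and 61 with only the 4 DP libraries.

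**Figure D4:**
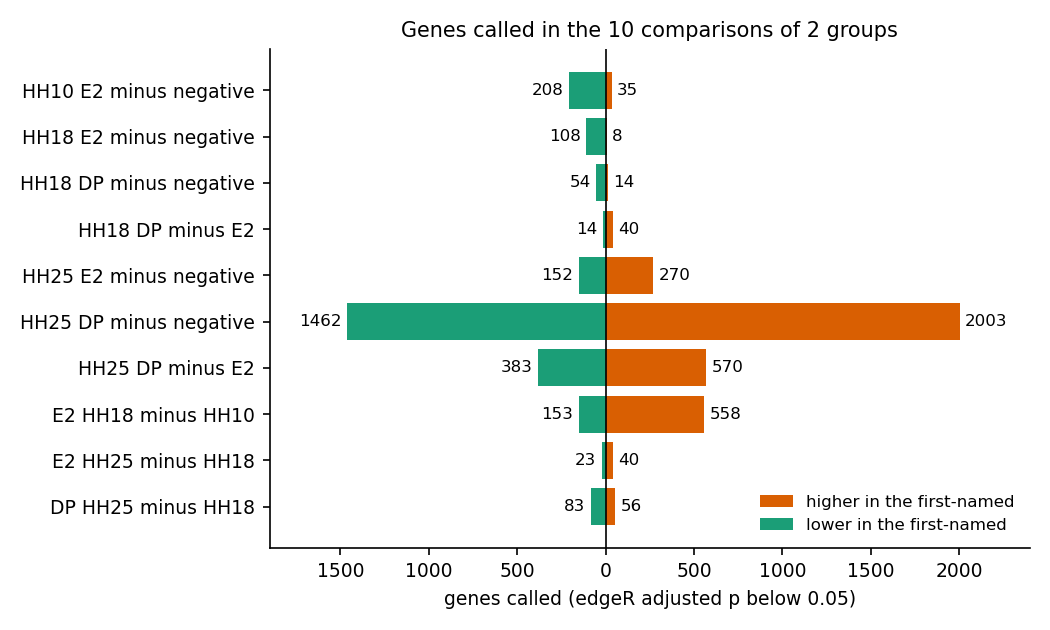
Number of genes called higher (right) and lower (left) in the first-named group of each of the 10 comparisons of 2 groups, on a linear axis. HH25 DP minus negative, with 2003 higher and 1462 lower, has the most calls, and HH18 DP minus E2, with 40 and 14, the fewest.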

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

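The tests weighed here were chosen after the results were seen, except the thinning of libraries and the spread of DP to negative ratios, whose criteria were written before their values were known. The tests of a difference between contrasts were planned.

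The difference between E2 and negative cells itself changed between HH10 and HH18 for 118 genes, as found by a test of the interaction in edgeR. For ENSGALG00000009002 on chromosome 1 the log2 difference, E2 minus negative, was larger at HH18 by 11.07. This gene had 0 counts in HH10 E2 and 8.14 ± 3.2 CPM in HH10 negative cells. At HH18 it was at 23.8 ± 0.86 CPM in E2 cells, with 18.5 and 9.54 CPM in the negative libraries. For ENSGALG00000011200 on chromosome 3 the difference was larger by 11.36. It had 0 counts in HH10 E2 and 12.6 ± 5.9 CPM in HH10 negative cells. At HH18 its levels were 4.7 ± 4.1 CPM in E2 and 3.5 ± 0.94 CPM in negative cells. Both changes thus came mainly from the 0 counts in HH10 E2 cells, whose libraries held the fewest genes at equal depth. ENSGALG00000003323 on chromosome 11 had a change of -14.84. It went from 2.74 ± 3.9 CPM in HH10 E2 cells, with 0 and 5.48 CPM in the libraries, to 0 counts at HH18. Negative cells reached 290 ± 196 CPM at HH18. ENSGALG00000005257 on chromosome 8 had a change of -16.79, and its HH10 E2 level came from 1 library too. The fitted values of these genes depend on the prior count because at least 1 group had no counts. The call of ENSGALG00000009002 passed without any 1 of the 8 libraries, and those of the other genes did not. The count was 204 and 207 without HH10 E2 library 1 and 3, 71 and 68 without HH10 negative library 1 and 3, 66 and 38 without HH18 negative library 1 and 2, and 71 and 73 without HH18 E2 library 1 and 2.

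Between HH18 and HH25 the difference between E2 and negative cells changed for 3 genes, all of them larger at HH25. For ENSGALG00000001030 on chromosome 28 the change was 12.07, and for ENSGALG00000041787 on chromosome 11 it was 11.31; both had 0 counts in HH25 negative cells and at least as many CPM in HH18 E2 (16.4 ± 6.0 and 17.8 ± 7.1) as in HH25 E2 cells (12.6 ± 3.8 and 11.6 ± 2.2). The count was 332 without HH25 negative library 2, 24 without HH25 negative library 1, 8 without HH25 E2 library 2, 1 without HH18 E2 library 2, and 0 without HH18 negative library 2 or HH18 E2 library 1, where both calls ended, as they did without HH18 E2 library 2. The difference between DP and E2 cells changed from HH18 to HH25 for 27 genes. It rose by 11.70 for ENSGALG00000006202 on chromosome 14, which had no count in HH18 DP cells, and by 5.14 for ENSGALG00000004270 on chromosome 10, which reached 137 CPM in HH25 DP cells. The change was -10.67 for ENSGALG00000002118 on chromosome 13, with no count in HH18 E2 cells, and -8.43 for ENSGALG00000040582 on chromosome 17, with no count in HH25 DP cells. Each of these 4 calls ended without HH18 E2 library 2, HH25 DP library 2 or HH25 DP library 3; the count was then 1, 6 and 1. It was 13 without HH18 E2 library 1, 17 without HH18 DP library 2, and 46 and 14 without HH25 E2 library 1 and 2.

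The first pattern weighed is the excess of lower genes in HH10 E2 cells. A difference in depth is argued against, since 192 genes were called after the 4 HH10 libraries were thinned to 12416163 counts each, 188 of them among the original 243. Capture of fewer transcripts in the HH10 E2 libraries remains a candidate explanation: at equal depth they held a mean of 11739 genes, each below the other 14 libraries. Library 3, at 12179 genes, lay only just below the lowest of these, at 12187. Of the lower genes, 12 were shared between HH10 and HH18, where 1000 random lists matched on mean expression gave 0 to 5 in their central 95%. At an adjusted p below 0.01, 3 were shared. The lists were matched on the mean over all libraries and not on the level in E2 cells. This excess therefore does not decide against capture of fewer transcripts. At HH25, 17 of the 208 genes were lower and 7 higher in E2 cells (random lists 0 to 7 lower). As a set they missed the threshold there (camera, adjusted p = 0.074, 0.44 with an estimated correlation, and 0.093 with fry). A loss of transcripts in E2 cells as the crest is specified remains open too and was not tested.

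The second pattern is the set of 40 genes higher in DP than E2 cells at HH18 and as abundant in negative cells. Carry-over of the whole negative population into the DP sort is argued against. The pattern's genes had a median DP to negative ratio of 1.63 (10th percentile 0.764), so that such carry-over would need a large share of negative cells and would bring their other abundant transcripts too. Of 92 genes lower in E2 than negative cells at HH25 and at 50 CPM or more in HH18 negative cells, chosen without the DP libraries and including 24 of the pattern, 42 stayed below 0.764 even for the higher DP over the lower negative library. The lower quartile of that ratio was 0.166. Presence of 1 cell type of the negative population in the DP sort cannot be told apart from expression by the DP cells themselves. The interquartile range of the log2 ratio over the 40 genes was 0.799, within the 0.745 to 1.59 of random lists matched on expression, and without gene names no marker can be read.

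The third pattern is the distance of HH25 DP from HH25 E2 cells, towards earlier stages. Depth is argued against as the cause of the calls as a whole, since 942 genes were called with the HH25 libraries thinned to 9153539 counts (907 of them among the original 953). A different mix of embryo sexes stays open: 918 genes were called without the genes of chromosomes Z and W, but those held 45 of the calls, and effects of sex on other chromosomes would remain. For the low chromosome W counts a larger share of male embryos in the DP samples may be the cause, and both DP libraries also had the highest share of chromosome Z counts (49383 and 52736 CPM). The HH10 negative libraries came close to the lower of these, at 48792 and 49096 CPM, with chromosome W counts of 471 and 412 CPM. A high share of chromosome Z counts thus also occurred without low chromosome W counts. Of the chromosome Z genes 36 were higher and 8 lower in DP than E2 cells, with a median log2 fold change of 0.41 against 0.17 for all genes. The camera set test missed the threshold in DP minus E2 (adjusted p = 0.196, and 0.55 with an estimated correlation). It passed the threshold in DP HH25 minus HH18 (adjusted p = 0.047, and 0.36 with an estimated correlation). With fry the set was higher in both comparisons (adjusted p = 0.043 and 0.016). In HH25 DP minus negative it was higher with fry (adjusted p = 0.0099) and missed the threshold with camera (adjusted p = 0.217). The tests differed, so that a larger share of male embryos stays open. DP libraries taken from an earlier stage cannot be told apart from a difference of the DP cells themselves, since no library gives an independent reading of stage. Their mean position of 0.255 lay below the lowest HH18 library (0.303) and the lowest HH25 E2 library (0.572). Both HH25 DP libraries also lay below the HH18 DP libraries (0.387 and 0.490), where a slower change along this axis alone would not place them. The axis was built on negative cells only and can mix differences between populations with stage. The positions thus argue against a slower change along this axis as the only cause. They do not decide against a slower change together with other differences between the populations. A biological difference between the populations is among the open explanations and was not tested.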

How the results depend on the processing

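Fits with the numbers in the column names as a block, the fits on 10 numbered libraries without a block, the crossed numbers and the gene groups were chosen after the data were examined; the other alternatives were planned. Tests of the fixed gene lists were not run, for lack of gene names. DESeq2 size factors kept each of the 13 counts within 1.5 times. The cause of the changes below was not tested, except that a fit with fewer libraries has fewer degrees of freedom. A lone library left in a group was assumed to vary like the other groups.

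Comparisons are given in the order E2 minus negative at HH10, HH18 and HH25, DP minus negative at HH18 and HH25, DP minus E2 at HH18 and HH25, E2 HH18 minus HH10, E2 and DP HH25 minus HH18, and the 3 differences between contrasts. With DESeq2's Wald test the counts were 875, 486, 1492, 430, 4933, 476, 2905, 2181, 540, 1233, 433, 376 and 769. Without a filter, 193 genes were called for HH18 E2 minus negative, 116 for HH18 DP minus negative, 94 for HH18 DP minus E2, 112 and 251 for E2 and DP HH25 minus HH18, and 48 and 98 for the last 2 differences between contrasts; the stricter filter gave 13 for the second of the 3. With only the groups compared the counts were 0 for HH10 E2 minus negative (1528 at an unadjusted p under 0.05), 677 and 64 for HH18 and HH25 E2 minus negative, 1559 for HH25 DP minus E2, 28 for E2 HH18 minus HH10, 61 for DP HH25 minus HH18, and 49, 0 (1651 unadjusted) and 1 for the differences.

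The labels' replicate numbers were not tied to a shared sort or day. Deviations of same-numbered libraries correlated at -0.033, -0.121 and -0.010 for the HH18 pairs E2 and negative, E2 and DP, and DP and negative, at -0.088 for HH25 E2 and negative, and at 0.285 for HH10 E2 and negative by column numbers. With the number as a replicate block common to the 10 numbered libraries, HH25 E2 minus negative had 275 calls (132 higher and 143 lower) and the E2 minus negative difference between HH18 and HH25 had 0 (1173 unadjusted). With the replicate block within stage these were 167 (57 higher and 110 lower) and 0 (946 unadjusted), and E2 HH25 minus HH18 had 1. The same 10 libraries without a replicate block gave 178 for HH18 E2 minus negative, 90 for HH18 DP minus E2 and 0 (1482 unadjusted) for that difference. A replicate block of column numbers within stage, which left few degrees of freedom, gave 59, 62, 152, 32, 692, 19, 0, 173, 0, 0, 46, 0 and 0 in the order above, with 69 higher and 83 lower for HH25 E2 minus negative, and 1607, 806, 923, 1104 and 1133 at an unadjusted p under 0.05 for the counts of 0. For HH18 DP minus E2 in its 4 libraries, the replicate block called 166 genes and crossed numbers 127.

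With each library left out in turn, the lowest and highest counts in that order were 127 and 354, 36 and 84, 142 and 703, 22 and 62, 1470 and 3440, 6 and 44, 0 and 624, 315 and 620, 0 and 73, 28 and 103, 38 and 207, 0 and 332, and 1 and 46. The named genes kept their direction in each refit, with the call kept in 407 and ended in 207 of them. Of the refits of gene group tests, 398 kept their side of the threshold, 45 lost and 16 gained a call, and 2 reversed, meaning that camera's direction relative to other genes changed while at least 1 of both tests passed the threshold, both for HH18 DP minus E2: genes lower at HH25 in negative cells without E2 library 1 (median log2 fold change -0.20, adjusted p = 0.012), and genes higher at HH25 in negative cells without E2 library 2 (-0.07, adjusted p = 0.61). Over the left-out libraries the median ranged from -0.20 to 0.24 for the former and from -0.232 (without DP library 2) to 0.386 (without E2 library 1) for the latter group. Thinning to equal depth was run for HH10 and HH25 (192 and 942 calls), and the effect of depth at HH18 was not tested. Positions moved by more than 1 SD in 3 of their refits and by less in 54. Counts of runs of neighbouring genes stayed within 1.5 times in 100 and changed more in 62 refits, and each of the 10 counts of shared calls changed by more than 1.5 times at an adjusted p below 0.01.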

Other observations

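The gene groups and the order of genes along chromosomes were looked at after the data were examined.

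Some of the genes that changed with stage in negative cells were also called in E2 cells. Of the 1802 genes higher at HH25 than HH10 in negative cells, 298 were higher and 10 lower in E2 cells at HH18 than at HH10. The camera adjusted p was 1.26e-21 (0.16 with an estimated correlation, and 0.0026 with fry). In E2 cells at HH25, 32 were higher and 1 lower than at HH18 (camera, adjusted p = 3.67e-24, 0.15 with an estimated correlation, and 0.032 with fry). In DP cells the same group went the other way between HH18 and HH25, with 54 genes lower and 20 higher. That change had a camera adjusted p of 2.52e-14 (0.29 with an estimated correlation, and 0.071 with fry). Of the 40 genes higher in DP than E2 cells at HH18, 36 belonged to this group. Of the 40 genes, 34 were lower in DP than negative cells at HH25 (camera, adjusted p = 2.26e-23, 0.0076 with an estimated correlation, and 6.96e-07 with fry).

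Other genes that stood next to each other moved together in HH25 DP cells. A group of 3 genes on chromosome 33 (1622780 to 1648011) summed to 328 ± 50 CPM in HH25 DP and 2598 ± 247 CPM in HH25 E2 cells. A group of 3 on chromosome 5 (16974079 to 16978970) summed to 116 ± 30 and 726 ± 106 CPM. For HH25 DP minus E2 no run was called without E2 library 2, DP library 2 or DP library 3, and 1 without E2 library 1. The chromosome 33 level was 475 ± 29 CPM and the chromosome 5 level 151 ± 41 CPM in HH10 negative cells. The chromosome 3 run that was abundant in HH25 negative cells was at 129 ± 141 CPM in HH18 negative cells and had no count at HH10.

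Of 6379 genes at 5 CPM or more in each of the other 14 libraries, 34 had no count in HH10 E2 library 1 and 13 none in library 3. The 2 libraries shared 3 of these, where 0.0693 would be shared by independent losses that are equally likely for each gene. Losses can depend on the level of a gene, so that this excess does not show a shared loss.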
